A study of Mus musculus with 2 samples.

How the data were processed

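Total RNA of whole skin was amplified, labelled with Cy3 and hybridised to Agilent mouse arrays, 1 labelled RNA per array, per the labels' protocols. Both samples came from 4-week-old females of the same stock. Each array's deposited file gives spot intensity on a linear scale, extracted with Agilent Feature Extraction 10.7.1.1 per the file headers, whereas the submitters' processing notes name version 9.5.1.1. The processed signal had its background subtracted and spatial trends removed within the array, with surrogate values for dim spots, per the file headers, and was not normalized between arrays. The flags for outliers, saturation and signal well above background are 0 or 1 per spot in the deposited files. The slide and the scan time were the same for both arrays, so there was no slide or scan batch. The authors' series table, also intensity on a linear scale, ranked the probes as the scanner signals did (Spearman correlation 1.00 for each array), and its sorted columns were equal within 0.1% at 100.0% of positions, as quantile normalization leaves them. Both of its columns had a median of 27.5. No normalization step of that table is given in the sources used here.

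Groups follow the sample titles. The source names give the opposite site for each sample, and no group was changed from the data. The main values were log2 of the processed signal minus each array's 75th percentile, a signal of 286.9 on the array titled flank and 271.5 on the array titled neck. Control spots and spots with an outlier flag (55 and 109) were left out, and spots of a probe were averaged. A gene's difference was the median over its probes well above background on at least 1 array. There were 32197 such probes, 29517 of them above background on both arrays. A probe dim on 1 array entered at its bound, the higher of its own signal and the lowest signal among probes well above background there, and a bound under 0 was set to 0. Folds of such probes are given as "at least". Of the genes, 7351 had more than 1 detected probe, and in 4 of them probes lay 2-fold apart in opposite directions. Signal over background limits what can be measured, since the lowest signals called well above background were 16.3 and 15.9.

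Probes were named through a reference gene table of assembly GRCm38.p6, used for names alone. By accession 32994 probes matched, by symbol 10224 and by an older symbol 520, and 12865 kept the name in the file. The 2 Flg probes were named through the description column of the array files, a choice made after the data were examined. Probe positions are those of the array files in the mm9 build, and exon or UTR annotation of that build was not used here.

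Fixed before the data were examined were the size rule of 2-fold, 40 gene lists, the alternatives and the rule for named genes. That rule took the 12 largest differences in each direction among genes measured on both arrays with all detected probes of the same sign, leaving out clone and model names and keeping at most 2 Krtap genes. It added up to 6 genes per direction with the largest bounds, up to 4 members of each list with the largest differences, the member with the highest mean log2 level, and Flg and Tmem79. Not every gene it allows is printed. Genes outside it, such as Hoxd8, Hoxd9, Hoxb9, Hoxc10, Ucp1, Serpina1e, Serpina1c, Fzd3 and Vmn1r52, were chosen after their values were seen. The pattern that recognises clone and model names was at first wider than the written rule and was corrected to it after the data were examined, which let Olfr1134 be named. A list with at least 5 detected genes was compared with 10000 random lists of the same size matched on mean expression in 20 bins, and 10000 draws of its members gave the range of its median. No p-value was computed.

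On simulated arrays with the measured spot noise, 21043 genes and 200 changed genes, 49 of 50 genes changed 3-fold were called at least 2-fold apart. Of those changed 6-fold and 12-fold, 48 of 50 were called at each size. Of 50 genes changed 1.5-fold and 20843 unchanged genes, 0 were called. Of 200 random lists of unchanged genes, 4 fell outside the central 95%. The simulation held spot noise alone, without variation between animals or pieces of skin, so it does not give the error rate of the real comparison. Alternatives were normexp background correction with an offset of 50, quantile and median scaling, other treatments of dim probes, the brightest probe per gene, the authors' values, folds of 1.5 and 4, unmatched random lists, and leaving out saturated probes, hair genes or muscle genes. Spike-in scaling and counting reference symbols alone were added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.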

Results

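Gene expression was measured in whole skin of 4-week-old female flaky tail mice, a stock that carries mutations in Tmem79 (matted) and Flg (flaky tail) and develops dermatitis without treatment. The skin was labelled non-lesional. The design compares skin of the neck with skin of the flank, and 1 array was hybridised for each site, so there were no replicates and no test across animals was possible. Each array held 62976 spots, of which 59305 were not controls and represented 56605 probes. Of these spots, 56.7% were well above background on the array titled flank and 56.3% on the array titled neck, and none was saturated. The number of arrays limits the precision of every value below.

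The largest differences were in genes of the hair follicle, which were far lower on the array titled neck. Markers of skeletal muscle, fat, connective tissue, mast cells and simple epithelium were moderately higher there, as were genes of the cornified envelope and filaggrin family and the chemokines Cxcl1 and Cxcl2. The sites are named by the sample titles. The source names of the same samples state the opposite sites, and every direction given here turns around if the source names are right. Of 21043 detected genes and transcripts, 550 were at least 2-fold higher and 931 at least 2-fold lower on the array titled neck, and 93.0% lay within 2-fold. At 8-fold or more the counts were 17 higher and 252 lower, and 114 were at least 64-fold lower. The 4 hair lists held 60 of these 114 genes, but 94 of the 931. The slope of the spike-in controls was flagged as out of range on both arrays (0.89 on the array titled flank, 0.87 on the array titled neck), so scaling by them is uncertain. After scaling to the 75th percentile, the 8 spike-in probes used were all higher on the array titled neck. Their log2 differences ran from 0.30 to 0.73, with a median of 0.35. With the arrays scaled to their spike-in controls in place of the 75th percentile, the counts were 172 higher and 1800 lower, since this scaling moved the median of all genes by -0.40 on the log2 scale. The list medians below moved by the same amount, except that of Langerhans and dendritic cells, which moved by slightly less. With another background correction (normexp) they were 169 higher and 516 lower. The only repeated measurement was the printing of 300 probes at 10 spots each. Over the 295 of them well above background on both arrays, the median SD of log2 signal between spots was 0.039 on the array titled flank and 0.066 on the array titled neck. No pair of such spots among 12810 differed by 2-fold on the former, and 8 of 12365 did on the latter. This spread covers printing and scanning of a labelled RNA, not animals or pieces of skin.

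**Figure D1:**
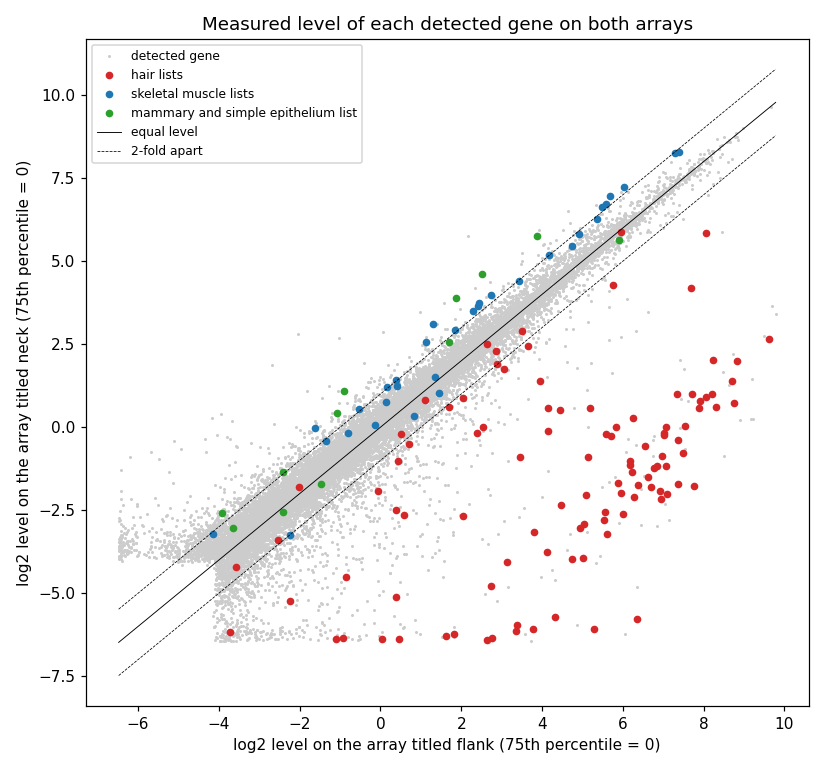
Measured log2 level of each detected gene on the array titled flank (x axis) and the array titled neck (y axis), each scaled so that its 75th percentile is 0; dashed lines mark 2-fold. Most points of the hair lists (red) lie far below the line of equal level, and 22 of 22 fast muscle genes (among the blue points) lie above it.

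Genes of the hair shaft and its sheaths were lower on the array titled neck almost without exception. Of 16 hair shaft keratins, 15 were at least 2-fold lower, with a median log2 difference of -6.96. Krt33a was 738-fold lower, with a signal of 62341 on the array titled flank and 79.9 on the array titled neck. Its probe lies on chromosome 11 at 99872578 to 99872637 of the mm9 build. Krt33b was 551-fold, Krt87 422-fold, Krt31 334-fold and Krt86 278-fold lower, whereas Krt85 differed by only -0.62. The Krt87 signal on the array titled neck (17.2) was close to the lowest called well above background there (15.9), so its fold is uncertain. All 54 detected keratin-associated protein genes, which encode the matrix between hair keratin filaments, were at least 2-fold lower (median -7.16). Krtap11-1 was 536-fold and Krtap13-1 455-fold lower. Krtap28-13 and Krtap26-1 were not well above background on the array titled neck and were at least 1387-fold and at least 664-fold lower. Krtap4-6 differed by -2.23. In the inner root sheath and companion layer list 13 of 16 genes were at least 2-fold lower (median -7.60). They included Krt27 (548-fold), S100a3 (459-fold), Tchhl1 (304-fold) and Krt71 (260-fold). Keratin and keratin-associated genes have near-identical family members, so the value of a single member is uncertain. The medians of these 3 lists lay below all of their 10000 random lists of matched expression (percentile 0.0). The genes of the 4 hair lists took 4.60% of the summed signal on the array titled flank and 0.192% on the array titled neck.

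The list fixed under the name hair matrix regulators was lower by less. Of 19 genes, 12 were at least 2-fold lower (median -1.19, percentile 0.0), among them the fibroblast growth factor Fgf5 (at least 9.52-fold, dim on the array titled neck), the desmoglein Dsg4 (-3.22) and the transcription factors Foxn1 (-2.88) and Msx2 (-2.57). Gata3 differed by -0.07. Other genes at the lower end were the receptor Gprc5d, 620-fold lower as the median of a measured and a bounded probe, and Olfr1134, 321-fold lower. Crnn, Krt73, Mecom and Krt82 were not well above background on the array titled neck and were at least 244-fold, 174-fold, 126-fold and 107.2-fold lower. The Mecom value rested on 1 of its 5 probes, and the other 4 were not above background on either array. The list of telogen bulge and hair germ genes did not stand apart (median -0.05, percentile 12.1), with Krt15 at 0.04, Aspn at 1.35 and Foxc1 at -1.60. None of 24 proliferation genes reached 2-fold (median 0.20, percentile 96.0), and Birc5 differed most, by 0.83. The melanocyte and pigment list was higher (median 0.48, percentile 99.81), with Sox10 at 1.12 and Kit at 1.02 against Mitf at -0.86. That list did not stand apart when dim probes were kept (median 0.13).

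Among genes measured on both arrays, the differences in the other direction were smaller. Krt6b, a keratin of the companion layer and of stressed epidermis, was 28.7-fold higher on the array titled neck, with signals of 69.5 on the array titled flank and 1886 on the array titled neck. Its probe lies on chromosome 15 at 101506492 to 101506551 of mm9. Ltf, which encodes the iron-binding protein lactoferrin, was 23.6-fold higher. The cornified envelope gene Sprr2d was 14.5-fold, the forkhead factor Foxi1 13.9-fold and the tryptophan-degrading enzyme Ido1 13.0-fold higher, and the protease inhibitor Stfa1 was at 3.59. Slc35f3 (10.2-fold), Nmrk2 (7.73-fold), Aoc1 (7.61-fold), Clca1 (7.49-fold), Serpinb6d (7.05-fold) and Clic6 (6.60-fold) followed. For Aoc1, 1 of the 2 probes was at a bound. On the array titled flank, Foxi1 (17.5), Slc35f3 (21.7), Sprr2d (22.4) and Nmrk2 (24.5) had low signals. The lowest signal called well above background there was 16.3, so the folds of these genes are uncertain. Genes not well above background on the array titled flank were led by Cstdc6 (at least 20.3-fold), the mucin Muc13 (at least 12.4-fold) and Serpinb3a (at least 11.4-fold). S100g (at least 11.1-fold), Tmprss11a (at least 9.44-fold) and Tph1 (at least 9.14-fold) followed. The probes of Cstdc6 and Stfa1 start near each other on chromosome 16 of mm9, at 36334350 and 36285398. Whether they bind each other's transcripts was not tested, so these values may not be separate.

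The cornified envelope and filaggrin family list was higher on the array titled neck (median 0.61, above all random lists). Of its 34 detected genes 16 were at least 2-fold higher and 3 at least 2-fold lower. Lce1g, a late cornified envelope gene, was at 1.70, while Sprr2h (-4.53) and Sprr1a (-2.25) went the other way and Lor, which encodes loricrin, differed by 0.26. The Sprr2 and Lce1 genes are near-identical in sequence, so their single values are uncertain. For the same reason the 16 genes are not as many separate measurements, and random lists do not share this limit. Flg, which carries a mutation in this stock, was higher, with its 2 probes at 0.96 and 1.04. The first of these probes lies on chromosome 3 at 93083694 to 93083753 of mm9. Tmem79 differed by -0.17, and its probe lies on chromosome 3 at 88132969 to 88133028. The epidermal keratin and desmosome list was slightly lower as a whole (median -0.23, percentile 0.07), although Krt1 was at 1.06 and Krt14 at -0.22. Of 13 tight junction genes, Cldn7 was at 1.73 and Cldn1 at -1.02 (list median -0.25, percentile 0.13). For both of these lists the range of the median over draws of the members included 0. Barrier lipid genes (median 0.06, percentile 54.1) and epidermal proteases and their inhibitors (median 0.07, percentile 60.3) did not stand apart. Within the latter, Klk13 was at 1.60 and Spink6 at -1.92, and the list did stand apart, with a median of -0.45, when only probes above background on both arrays were used.

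Genes of stressed epidermis and alarmins moved in both directions. Of 21 detected genes 6 were at least 2-fold higher and 5 at least 2-fold lower, and the list median of -0.35 (-0.12 with normexp, -0.15 with dim probes kept or left out) had a range over draws of the members from -0.78 to 0.85. Krt6b and Stfa2 (2.53) were higher, and Krt17 was at -0.89. Whether the probes of Stfa1 and Stfa2, both in this list, bind each other's transcripts was not tested. S100a7a, dim on the array titled neck, was at least 17.5-fold lower. Interleukin 17 and interleukin 1 genes were higher on the array titled neck (median 0.69, above all random lists), and 5 of 14 were at least 2-fold higher. The other 12 genes of that list on the array were not detected, and its median was 0.28 with dim probes kept, 0.44 with normexp and 0.30 with spike-in scaling. The neutrophil chemokine Cxcl1 was at 2.15 and the cytokine Il6 at 2.03, the median of a measured and a bounded probe. The related chemokine Cxcl2 was at least 6.85-fold and Il19 at least 2.91-fold higher, both dim on the array titled flank. Type 2 and itch genes did not stand apart (median 0.18, percentile 87.2), with Retnla at 1.74 against Chil3 at -1.80. No interferon-stimulated gene of 26 reached 2-fold (median -0.10, percentile 1.27), and Isg15 was at -0.83. The range of this median over draws of the members included 0, and the list did not stand apart with dim probes kept. Complement and acute phase genes did not stand apart (median 0.20, percentile 93.0), but did with normexp (percentile 98.1) and with the brightest probe per gene (percentile 97.9). Immediate early and heat shock genes were slightly lower, 18 of 20 below 0 (median -0.30, percentile 0.0), with Atf3 at -0.81 and Hspb1 at -0.45.

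Among immune cell lists with at least 5 detected genes, mast cell genes differed most (median 0.94, above all random lists). Their median was 0.51 with normexp and 0.54 with spike-in scaling. Cpa3, the mast cell carboxypeptidase, was at 1.37, Ms4a2 at 1.28 and Mcpt4 at 0.998, while Mcpt1, dim on the array titled neck, was at least 2.73-fold lower. Macrophage markers were higher (median 0.49, above all random lists), with Cd14 at 1.31 and Pf4 at 0.89. Langerhans and dendritic cell markers were higher by 0.35 (percentile 98.8), with H2-Ab1 at 0.79. Spike-in scaling turned their median to -0.0345 and left the list outside the random range. T cell (median 0.28, percentile 95.2), neutrophil (0.22, percentile 86.0) and B and plasma cell lists (-0.30, percentile 3.87) did not stand apart, although the last did with normexp (percentile 1.39). Cd3e was at 0.78 and Csf3r at 0.01. Ltf was also a member of the neutrophil list, in which Ly6g was at 0.77. The probes of Cd4 disagreed, with 1 at -0.11 and 1 measured on the array titled flank alone. Only 3 eosinophil and basophil genes were detected, too few for a percentile, and Ear1 was at 1.67 and Ear2 at 1.40.

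All 22 fast skeletal muscle genes were higher on the array titled neck, 11 of them at least 2-fold (median 1.01, above all random lists). The calcium pump gene Atp2a1 was at 1.80, the glycogen phosphorylase gene Pygm at 1.44, Acta1 at 1.27 and Tnnc2 at 0.88. Slow and cardiac type muscle genes had a median of 0.62 (percentile 99.99; 0.36 with normexp), with Ankrd2 at 1.61 and Mb, which encodes myoglobin, at 1.23. All 20 white adipose genes were higher (median 0.64, above all random lists), among them Pck1 (1.05), Cidec (0.96) and Cfd (0.31). Brown adipose genes had a median of 0.89 (above all random lists; 0.37 with normexp), led by Cox7a1 (1.52) and Cpt1b (1.41), which muscle also expresses, while Ucp1 was not above background on either array. All 22 fibroblast and matrix genes were higher (median 0.50, above all random lists), with Dpt at 1.12 and Dcn, which encodes decorin, at 0.90. Endothelial genes were higher by 0.41 (percentile 99.91), with Kdr at 0.79, and Eng (-2.65, 1 of 2 probes) was an exception. The endothelial median was 0.28 with normexp and 0.21 with dim probes kept, where the list no longer stood apart. The list of mammary and simple epithelium was higher (median 1.09, above all random lists; 0.69 with normexp), and 6 of 12 genes were at least 2-fold higher. They included Krt8 (2.11), Krt19 (2.02), Krt7 (1.999) and Krt18 (1.89), keratins of glandular epithelia, while Wfdc18 was at -0.27. Salivary gland genes had a median of 0.58 over 7 detected genes (percentile 99.6), none of them 2-fold apart, and did not stand apart with dim probes kept (0.18). With normexp their median was 0.31. For the slow muscle, brown adipose, salivary gland and pigment lists, the range over draws of the members included 0.

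Sebaceous gland genes were lower on the array titled neck (median -0.58, percentile 0.0), 15 of 17 being below 0. Awat2, a wax synthase gene, was at -1.03, while Fasn was at 0.47. The 4 probes of Scd3 disagreed, from -5.28 to 0.08, with 1 of them at a bound. The list median was -0.29 with normexp, -0.34 with probes above background on both arrays alone and -0.18 with dim probes kept. Cholesterol synthesis genes were slightly lower (median -0.18, percentile 0.13), with Insig1 at -0.99. Nerve and Schwann cell genes did not stand apart (median 0.11, percentile 64.5), with Uchl1 at 1.27 and Gjb1 at -0.99. Genes for nerve guidance and itch ligands were higher (median 0.45, percentile 99.79; 0.29 with normexp), 10 of 13 being above 0. Only 1 was at least 2-fold higher, and 2 were at least 2-fold lower. Tac1, the substance P precursor, was at 1.57, on 1 of 4 probes with signals of 30.9 and 86.9. Against it stood Nppb at -2.09, the median of a measured and a bounded probe, and Edn1 at -1.22. The blood list did not stand apart (median 0.24, percentile 94.5). Its globin genes Hba-a1 (0.29) and Hba-a2 (0.25) were slightly above 0. Ahsp (-4.04) and Slc4a1 (-3.46), each on 1 probe, were the only 2 of its 8 detected genes lower on the array titled neck.

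Of the 39 lists with at least 5 detected genes, 27 lay outside the central 95% of random lists, 12 lower and 15 higher on the array titled neck, where 1.95 would be expected by chance. Genes within a list are not independent replicates, so these percentiles describe this pair of arrays.

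**Figure D2:**
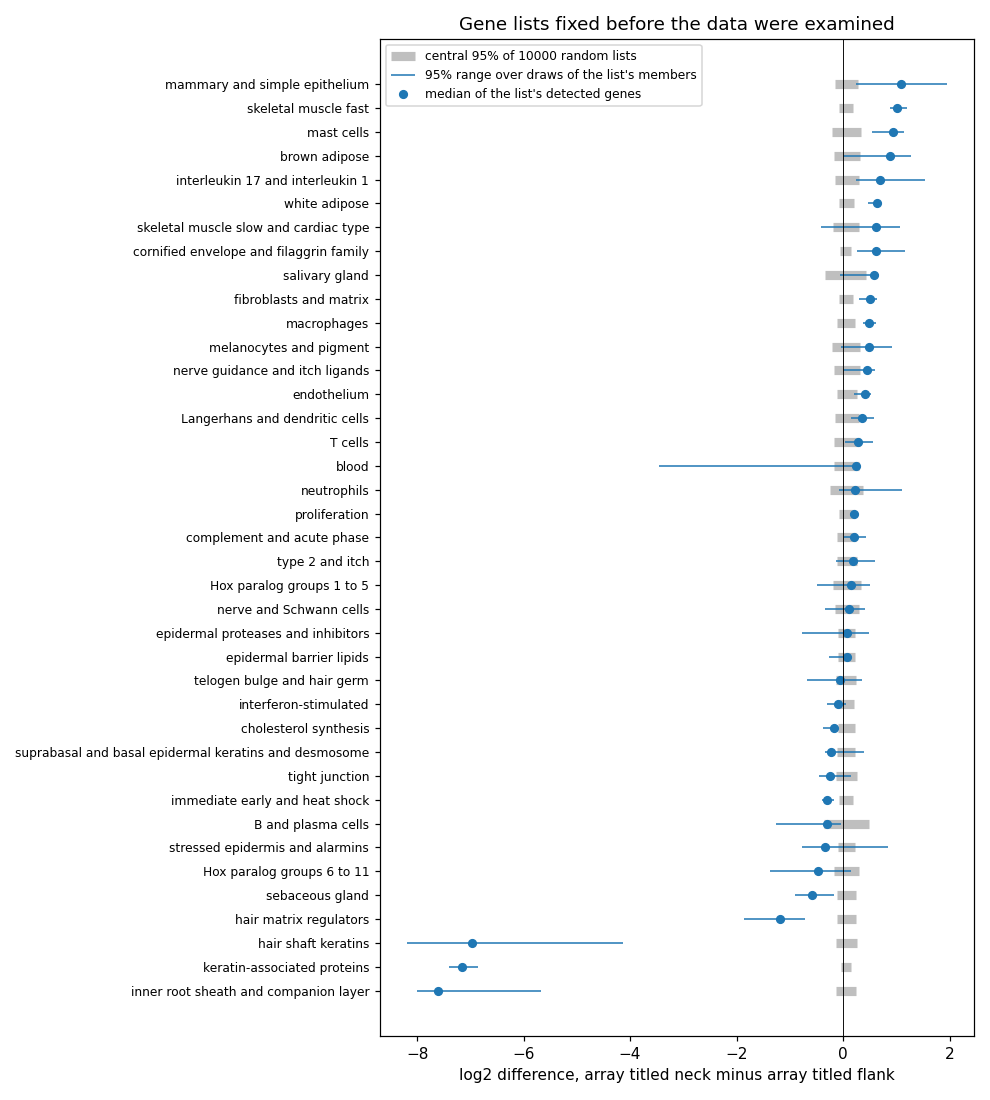
Median log2 difference of each gene list's detected genes (points), the array titled neck minus the array titled flank, with the 95% range over draws of its members (thin lines) and the central 95% of 10000 random lists of matched expression (grey bars). The 3 lists of hair shaft and sheath genes lie near -7, and the medians of the other lists lie between -1.19 and 1.09.

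Hox genes mark position along the body axis, and those of paralog groups 6 to 11 are used in the trunk, so they were fixed as a check of the sample titles. Of 14 detected genes of groups 6 to 11, 9 were lower and 5 higher on the array titled neck, with a median of -0.48 (percentile 0.02), or -0.24 with normexp. Hoxa7 was at -2.01, Hoxb6 at -1.91 and Hoxb7 at -1.56, whereas Hoxd8 (1.04), Hoxd9 (1.30) and Hoxb9 (0.58) were higher. Draws of the list's members gave medians from -1.38 to 0.15, a range that includes 0. The 11 detected genes of groups 1 to 5 did not stand apart (median 0.16, percentile 75.9), with Hoxc4 at 0.86 and Hoxa5 at -1.08.

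**Figure D3:**
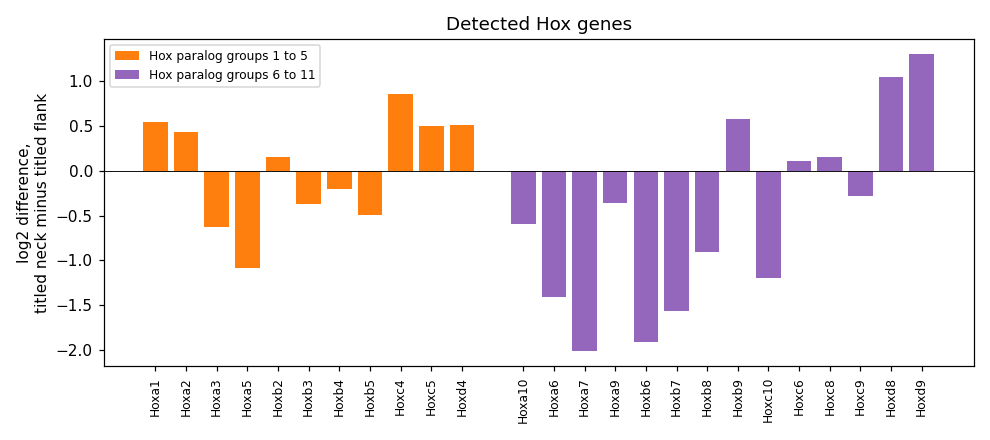
Log2 difference, the array titled neck minus the array titled flank, of each detected Hox gene (bars) of paralog groups 1 to 5 and 6 to 11. Hoxa7, Hoxb6 and Hoxb7 lie at or below -1.56, and Hoxd8 and Hoxd9 lie above 1; the bars of Hoxa6 and Hoxc10, dim on the array titled neck, show bounds.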

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

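Spike-in scaling and the count of reference symbols alone were chosen after seeing the data. If the source names give the sites, 0 of the 1481 genes 2-fold apart keep their direction. Quantile and median scaling, the authors' values, leaving out hair genes or muscle genes, and taking the brightest probe moved no list median they could test by more than its SD over draws of the members, and no count by more than 1.5 times, and no spot was saturated, so leaving out saturated probes moved nothing. With the brightest probe, Hox groups 1 to 5 (-0.16), bulge (0.018) and barrier lipids (-0.02) changed sign, all inside the random range. The number of lists outside the central 95% stayed between 23 and 29 in all settings tried. No paired analysis was possible because each site had 1 array, and the slide could not be used as a block.

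With normexp, whose offset compresses dim signals, 169 genes were higher and 516 lower. Of 206 genes that the naming rule allows, 148 moved by more than 0.080, the median SD of the difference of a single spot. List medians that moved were keratin-associated proteins -6.46, inner root sheath -6.71, proliferation 0.14, macrophages 0.39, mast cells 0.51, fibroblasts 0.40, endothelium 0.28, white adipose 0.57, brown adipose 0.37, sebaceous gland -0.29 and salivary gland 0.31. With probes above background on both arrays alone, epidermal proteases were at -0.45 and sebaceous gland at -0.34. With no filter on dim probes, 1550 genes were higher and 1702 lower, pigment was at 0.13, interleukin 17 and interleukin 1 at 0.28, T cells at 0.13, Langerhans and dendritic cells at 0.52, mast cells at 0.73, endothelium at 0.21, sebaceous gland at -0.18 and salivary gland at 0.18. The log2 difference of Mecom (0.0647) and the log2 difference of Cr2 (0.0215) changed sign, since their dim probes then entered. The pigment, endothelium, salivary gland and interferon lists then no longer stood apart. Complement and acute phase and B and plasma cells newly stood apart with normexp, epidermal proteases with probes on both arrays alone, and complement and acute phase with the brightest probe. With measured values in place of bounds 829 genes were higher. At 1.5-fold the counts were 2123 higher and 1860 lower, and at 4-fold 50 and 400.

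Spike-in scaling shifted genes measured on both arrays down by a common amount, and some at a bound by less, and gave 172 higher and 1800 lower. The same 27 lists lay outside the random range, and 1 of them, Langerhans and dendritic cells, changed sign (-0.0345). Lists inside that range that changed sign were Hox groups 1 to 5, proliferation, barrier lipids, proteases, type 2, complement, T cells, neutrophils, nerve and blood (-0.16). The medians that follow are only those that moved by more than their SD over draws of the members and kept their place outside the range or are named above. Above 0 stayed pigment 0.0867, cornified envelope 0.22, interleukin 17 and interleukin 1 0.30, macrophages 0.10, mast cells 0.54, fibroblasts 0.10, endothelium 0.0187, nerve guidance and itch ligands 0.0498, fast muscle 0.61, slow muscle 0.22, white adipose 0.24 and salivary gland 0.18. Below 0 were Hox groups 1 to 5 -0.24, keratin-associated proteins -7.56, hair matrix regulators -1.59, bulge -0.45, proliferation -0.20, epidermal keratins and desmosome -0.63, tight junction -0.64, barrier lipids -0.33, proteases -0.32, type 2 -0.22, interferon -0.49, complement -0.20, immediate early -0.69, T cells -0.12, B and plasma cells -0.70, neutrophils -0.18, nerve -0.29, sebaceous gland -0.98 and cholesterol synthesis -0.57. Where no construction of the setting is named, the cause was not tested.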

Other observations

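Genes outside the fixed lists were grouped by the stem of their symbol after the data were examined, and 479 families of at least 5 detected genes were compared with random lists. Below percentile 0.1 lay 3 families and above the matching upper bound lay 10. By chance 0.958 in all would be expected if the members of a family were separate measurements. The serpins of group A had a median of -0.97 over 18 genes, 9 of them at least 2-fold lower on the array titled neck. Serpina1e (-4.83) and Serpina1c (-4.29), which encode forms of alpha-1-antitrypsin, were among them and share near-identical sequence. Frizzled receptors of Wnt ligands were lower, with a median of -0.56 over 11 genes and Fzd3 at -1.71. Hes genes, many of them targets of Notch, had a median of -1.32 over 5 genes. Higher on the array titled neck were the Mup family of major urinary proteins (median 0.90 over 13 genes), Tbx factors (0.70 over 8), Wfdc genes (0.64 over 7), matrix metalloproteinases (0.56 over 12) and serpins of group B (0.49 over 16). Few of these genes reached 2-fold higher: 3 Mup, 0 Tbx, 2 Wfdc, 0 metalloproteinase and 4 group B serpin genes. At least 2-fold lower were 1 Tbx and 1 group B serpin gene. Whether probes of the Mup or other families bind transcripts of related members was not tested. The genes of a family may thus not be separate measurements, a limit that random lists do not share.

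Of 1382 olfactory, vomeronasal and trace amine receptor genes on the array 75 were detected, and 13 were at least 2-fold lower on the array titled neck against 1 higher. Among the lower ones Olfr1134 had signals of 25236 and 74.4, and Vmn1r52, dim on the array titled neck, was at least 103.5-fold lower. Whether these probes bind transcripts of other genes was not tested.

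The tests below were chosen after the result was seen, except that of the Hox genes, which was fixed before. The loss of hair gene signal on the array titled neck was not an effect of scaling, since the pooled median of the 3 lists of shaft and sheath genes was -7.14 under the scaling that gave the smallest loss. Sequence shared among keratin probes does not lower other genes. Yet 5 of 7 other members of the inner root sheath and companion layer list (S100a3 at -8.84, Tchhl1 at -8.25) were at least 2-fold lower. So were 12 of 19 genes of the hair matrix list, 17 of 26 in all against at most 7 in random lists. How much shared sequence adds to the loss of the keratin probes stays open. The 26 genes, 19 of them from the hair matrix list, had a median of -1.27, with a range over draws from -2.69 to -0.93. The sample titled neck may have held fewer dividing, pigment-making follicles, but the proliferation median was 0.20 (-0.20 under spike-in scaling) and the pigment median 0.48 with a range from -0.046 to 0.91, so neither decided it. Tyr, Oca2, Slc45a2, Gpr143 and Mc1r, named after their values were seen, were not well above background on either array, and another stage of the hair cycle at each site stays open and untested.

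The higher muscle and fat markers on the array titled neck were set beside a smaller share of hair RNA. Such a loss would raise all other transcripts alike, by 0.16 if all genes at least 2-fold lower are counted as lost. Scaling each array to its own percentile largely takes out a rise shared by all, and a difference from nerve markers cancels it. The values without spike-in scaling therefore cannot decide whether the share of hair RNA played a part. They show only how far the lists differed from other genes. Fast muscle moved apart from nerve markers by 0.90 (range 0.54 to 1.42) and white adipose by 0.53 (0.16 to 0.99). The ranges of brown adipose (0.78, from -0.25 to 1.35) and slow muscle (0.51, from -0.54 to 1.097) included 0. With 0.16 subtracted, 4 of 11 brown adipose, 2 of 10 slow muscle and 0 of 20 white adipose genes were 2-fold higher, where the central 95% of random lists held 0 to 1. The highest random count was 3 for brown adipose and 3 for slow muscle, so slow muscle did not exceed it. In these tests brown adipose and slow muscle stood apart by the count alone, and white adipose by the difference from nerve markers alone. Against random lists of matched expression, the medians of all these lists lay above the central 95% on this pair of arrays. White and brown adipose lay above all random lists. The ranges over draws of the brown adipose and slow muscle medians included 0, so their difference from other genes is less certain. Under spike-in scaling fast muscle was still at 0.61 (0.48 to 0.79) and white adipose at 0.24 (0.078 to 0.32). These ranges come from draws of members under a fixed shift, so they leave out the spread of the spike-ins themselves. Single spike-in probes ran from 0.30 to 0.73 before that shift. The highest lay above the white adipose median of 0.64, so scaling as its whole cause stays open. The fast muscle median of 1.01 lay above all of them. For fast muscle this argues against scaling as the whole cause, as far as spike-ins with a slope flagged out of range can tell. Brown adipose (2 of 11 genes 2-fold higher, a count that random lists also reached, median 0.49, from -0.41 to 0.89) left the part of scaling open. Slow muscle (1 of 10 genes, median 0.22, from -0.80 to 0.67) left it open too. More muscle and fat in the piece of skin titled neck stays open and untested, and 1 piece of skin per site does not separate depth of sampling from body site.

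The trunk Hox genes bear on the conflict between titles and source names. If the source names gave the site, the list of groups 6 to 11 should have been higher on the array titled neck, and its median was -0.48. The range over draws of its members, from -1.38 to 0.15, includes 0, and members went both ways, so the correct site cannot be told apart from these genes. Hoxc13, a hair matrix gene outside this list chosen after its value was seen, was at -2.51, and other Hox genes could differ with the hair follicles too.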
